A study of Homo sapiens with 6 samples.

How the data were processed

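Total RNA of AC16 cells was made into 6 messenger RNA sequencing libraries, 3 control (ethanol) and 3 PA, per the labels. Each library has a table with a gene identifier, a gene name and a value. The values are RPKM with 2 decimals as deposited by the authors, that is, reads scaled by transcript length and by library size. The tools FastQC, fastp, HISAT2, StringTie and RSEM and the build hg19 are named without role, order or version, per the submitters' processing notes. The gene models, the use of strand and the treatment of reads that match several genes are not given in the sources used here. The tables list 29638 rows, of which 28828 carry an Ensembl identifier and 28380 of these matched GENCODE 29 without the version. The GENCODE 29 annotation is built on another assembly than the one named, so no coordinates are given. It was used for gene types, overlaps, transcript lengths and GC content, and for gene symbols, meaning names approved by HGNC.

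RPKM values are not counts, so no count model was used. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided) on log2(RPKM + 1), over the 14159 genes with a mean RPKM of at least 1 in all 6 libraries together, without covariates. Benjamini-Hochberg adjustment was used with a threshold of 0.05. Errors are SDs of RPKM over 3 libraries and limma standard errors of log2 fold changes. An exact permutation test of 3 against 3 cannot go below p = 0.1 and was not used. Gene lists with at least 5 tested members, 34 of 36, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. fry tests whether a list moves on balance in one direction and does not compare it with other genes.

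The design, the 36 lists, the rule for named genes and the alternatives named first below were fixed before the data were examined. The rule took the 12 highest and 12 lowest log2 fold changes among genes past the threshold that had a gene symbol and no overlap between the groups, leaving out pseudogenes and antisense transcripts. It added EIF2AK2, MAPK8, MAPK9, SIRT1, CDKN1A and CDKN2A. From each list it took up to 4 passing members with the largest absolute log2 fold change, or up to 2 tested members where none passed. It also took the 5 genes with the highest mean RPKM. The text draws on 110 genes named by the rule; a further gene and a list tied to it are not reported here.

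On simulated data made from the means and SDs of the 14159 genes tested, with 200 genes changed in each of 10 runs, the fit for PA against control recovered 10.0% of genes changed by 0.5 log2 units, 60.9% of those changed by 1 and 93.3% of those changed by 2. Of its calls 3.37% were false. A list shifted by 0.4 log2 units was called in 10 of 10 runs. In this setting small changes of single genes were thus mostly missed. The real data gave 681 calls, more than the 200 genes changed per run. The adjusted threshold is less strict when more genes change, so recovery in the real data may be higher. The simulation used means and SDs of single genes and not the correlation between genes. Estimated correlations within the fixed lists reached 0.701 (ribosomal proteins), so the list and false-call rates may not hold for the real data.

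Alternatives covered the pseudocount, the filter, scaling, the variance model, the replicate number as a block, each library left out, and stricter thresholds. Added after the data were seen were protein-coding genes alone and the removal of a length and GC trend, fitted to each library's deviation from the gene mean with splines of 4 degrees of freedom. Lengths and GC contents for this were medians over each gene's protein-coding transcripts, or over all its transcripts where it has none of that type, and covered 95.2% of the tested genes. A version restricted to transcripts tagged basic, which leaves out most partial models, was tried only after the result of the first had been seen, and both are given. Relative depth was estimated from the most common ratio between libraries of RPKM values between 0.2 and 1.2, under the assumption that depths are similar, with 3 choices of genes. It rests on values that RSEM-type estimates can make fractional, so it is approximate, and no counting interval is given.

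A value of 0 in such tables can be a failed estimate: 34 rows with a mean of at least 10 RPKM were listed at 0 in some library. Among the rows tested, 45 had the same values as another row in all libraries. Calls include 22 rows without an Ensembl identifier, 15 pseudogenes and 16 antisense genes, which are counted; of these the metallothionein pseudogene MT1L is named, as a member of a list.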

Results

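RNA sequencing was carried out on AC16 cells, an established human cell line made by fusing adult ventricular cardiomyocytes with SV40-transformed fibroblasts. The data comprised 6 libraries, 3 from cells given ethanol, the vehicle (control), and 3 from cells given a fatty acid (PA). The series title names palmitic acid, the saturated fatty acid, whereas the treatment label names palmitelaidic acid, a trans-monounsaturated acid of the same chain length, so the treatment is called PA throughout. Dose and exposure time are not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Expression was given as RPKM for 29638 gene rows, with sums per library between 733025 and 881369, which are not read depths. Read depth itself is unknown. Steps in the low values gave the depth of each library relative to the average of the remaining libraries. PA 1 was at 1.13 to 1.19 and the other 5 libraries lay between 0.929 and 1.01, depending on which low genes were used.

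The comparison of PA with control asked which transcripts differed after exposure to the fatty acid. Of 14159 genes tested with limma, 681 passed an adjusted p of 0.05, with 402 higher and 279 lower in PA. The lowest fold changes belonged to ANGPTL4, a secreted inhibitor of lipoprotein lipase, CSF2, a cytokine, and CA9, a hypoxia-inducible carbonic anhydrase. ANGPTL4 fell from 20.6 ± 2.90 to 5.08 ± 0.320 RPKM (SD, n = 3 per group), a log2 fold change of -1.82 ± 0.13 (SE) with a limma adjusted p of 0.00444. GREM1, a secreted BMP antagonist, fell from 284.0 ± 16.4 to 102.8 ± 6.44 RPKM, a log2 fold change of -1.46 ± 0.10 with a limma adjusted p of 0.00444. The highest fold change was that of OSCAR, an immunoglobulin-like receptor, at 5.38 ± 0.485 RPKM in control and 17.2 ± 1.70 RPKM in PA, a log2 fold change of 1.51 ± 0.12 with a limma adjusted p of 0.00727. EGR1, an immediate early transcription factor, rose from 62.1 ± 4.70 to 149.5 ± 13.1 RPKM.

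The other genes with the highest log2 fold changes were CHCHD10 (1.40), SPX (1.30), CDC42EP5 (1.23), DNPH1 (1.22), FUOM (1.19), TNNI3 (1.18), PTP4A3 (1.17), TSGA10 (1.16), DMGDH (1.16) and REEP6 (1.15). The other genes with the lowest values were CSF2 (-1.68), CA9 (-1.61), NEXN (-1.53), DOK3 (-1.52), CEMIP (-1.47), TNFRSF11B (-1.37), COL3A1 (-1.37), MMP3 (-1.36), SCG5 (-1.31) and CPA4 (-1.31). These fold changes are on the log2(RPKM + 1) scale and understate the change of genes with low values, such as COL3A1, at 3.81 ± 0.247 RPKM in control and 0.860 ± 0.0781 RPKM in PA. Exons of CHCHD10, SPX, TSGA10, DMGDH, REEP6, ANGPTL4, CA9, NEXN, DOK3, CEMIP, GREM1 and MMP3 overlap a listed gene on the opposite strand, and those of TNNI3 overlap one on the same strand. Of the 110 named genes, 43 overlap another listed gene. The use of strand in counting is not given in the sources used here, so reads of such pairs may not be separable. All 681 genes had 3 PA values on one side of the 3 control values, as did 32.6% of the genes tested, where chance gives 10%.

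**Figure D1:**
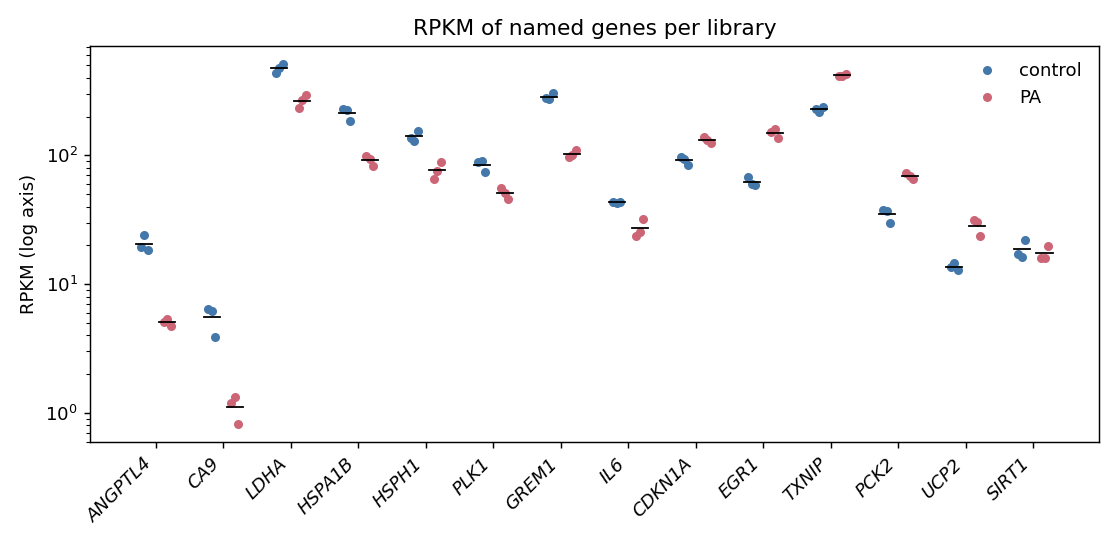
RPKM of 14 named genes in the 3 control and 3 PA libraries, on a log axis, with one point per library and a bar at each group mean. ANGPTL4 lay between 18.5 and 23.9 RPKM in control and between 4.77 and 5.41 RPKM in PA, while the SIRT1 values of the groups overlapped.

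The number of genes past the threshold depended on every library. It was 15 without control 1, 78 without control 2, 80 without control 3, 202 without PA 1, 10 without PA 2 and 364 without PA 3. ANGPTL4, GREM1 and OSCAR passed the limma threshold in all 6 of these fits, and 349 of the 681 genes passed in 0 of them. With values rescaled to a common sum, 39.2% of the calls were higher in PA, against 59.0% in the values as deposited, and the median log2 fold change of all genes moved from -0.02 to -0.12. Without the filter on low values 72 genes passed.

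Among the genes of the series title, none passed the limma threshold. EIF2AK2, which encodes the kinase PKR, was at 24.4 ± 3.03 RPKM in control and 19.0 ± 1.09 RPKM in PA, a log2 fold change of -0.34 ± 0.12 with a limma adjusted p of 0.131. MAPK8, which encodes JNK1, was at 61.5 ± 8.41 and 46.3 ± 3.88 RPKM, a log2 fold change of -0.40 ± 0.13 with a limma adjusted p of 0.112. The log2 fold change was -0.09 ± 0.13 for MAPK9, which encodes JNK2, and -0.09 ± 0.15 for SIRT1, the deacetylase, with limma adjusted p-values of 0.679 and 0.721. The sign of the SIRT1 value turned without control 3 (0.03) and after removal of a length and GC trend (0.06). That removal moved MAPK8 to -0.20, MAPK9 to -0.01 and EIF2AK2 to -0.29 (-0.18 with lengths from basic transcripts). RPKM measures transcripts and not the activity of these kinases or of SIRT1. The fixed list of this pathway had 0 of 14 tested members past the threshold, also 0 adjusted over the list alone, and the sirtuin list 0 of 7, also 0 adjusted over the list alone, with camera adjusted p-values of 0.358 and 0.774. FOXO3 (-0.38), SIRT5 (0.38) and SIRT6 (0.13) did not pass. FOXO3 was at -0.23 and SIRT6 at -0.03 after removal of the trend, FOXO3 at -0.22 without PA 3 and SIRT5 at 0.21 without control 1.

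CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 92.0 ± 6.32 to 131.7 ± 6.98 RPKM, a log2 fold change of 0.51 ± 0.10 with a limma adjusted p of 0.0352. The call held in 1 of the 6 fits that each left out a library. CDKN2A, which encodes p16 and p14ARF, was at 245.5 ± 40.6 RPKM in control and 353.1 ± 42.6 RPKM in PA and did not pass (limma adjusted p = 0.0781). Of 17 tested senescence effectors and markers, CDKN1A was higher and HMGA2, a chromatin protein, was lower (-0.54), and 2 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.257). Senescence-associated secretory factors went both ways: of 31 tested, 8 were higher and 8 lower, or 11 and 10 adjusted over the list alone, and the camera adjusted p was 0.879, with a median of 0.04 and a mean of -0.08. That median has no stable sign: it was 0.12 without control 2, -0.0013 without PA 3 and 0.13 after removal of the length and GC trend. Rescaled to a common sum it was -0.06, where the median of all genes was -0.12. CSF2, TNFRSF11B, MMP3 and INHBA (-1.24) fell, while the interleukin gene IL1B rose from 251.3 ± 14.0 to 369.1 ± 18.5 RPKM.

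Heat shock genes were lower in PA. Of 21 tested, 7 fell and none rose, 9 fell adjusted over the list alone, and the median log2 fold change was -0.38 (camera adjusted p = 1.81e-06, and adjusted p = 0.255 with an estimated correlation). The chaperone genes HSP90AA1 and HSPH1 fell from 1534 ± 168.2 to 871 ± 170.2 RPKM and from 140.6 ± 13.1 to 76.4 ± 11.7 RPKM. HSPA1B (-1.21) and HSPA1A (-1.01) fell as well, but these near-identical copies share reads and their separate values are uncertain. Glycolysis and hypoxia response genes fell in 8 of 35 tested members with none higher, or 10 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.000547, and adjusted p = 0.547 with an estimated correlation). They included CA9, PFKFB4 (-1.02), ADM (-0.71) and LDHA, which makes lactate from pyruvate and fell from 473.6 ± 39.1 to 265.6 ± 28.9 RPKM. Of 31 tested NRF2 and oxidative stress genes, 1 passed, GCLM (-1.05), a subunit of the enzyme that limits glutathione synthesis, and 25 had negative values. In that list 2 were lower adjusted over the list alone (camera adjusted p = 0.00984, and adjusted p = 0.276 with an estimated correlation), and it did not pass without control 2 (camera adjusted p = 0.0511).

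Mitotic genes fell in 8 of 42 tested members, and in 10 adjusted over the list alone, with none higher (camera adjusted p = 6.59e-06, and adjusted p = 0.276 with an estimated correlation). CENPE (-1.11), KIF20B (-0.86) and ASPM (-0.80) have long transcripts, and PLK1, a mitotic kinase, fell from 84.3 ± 8.56 to 51.1 ± 4.74 RPKM. Of 40 DNA replication genes, 1 rose, CCNE1 (0.74), also 1 adjusted over the list alone (camera adjusted p = 0.46). Replication-dependent histones had 0 of 12 past the threshold, also 0 adjusted over the list alone (camera adjusted p = 0.102), and their near-identical copies make single values uncertain. HIST1H4H (-1.11) and HIST1H2BJ (0.57) did not pass.

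Of the lipid-related lists, PPAR targets and fatty acid oxidation passed camera as higher in PA and the others did not pass. Among 26 tested PPAR targets and fatty acid oxidation genes, 6 rose and ANGPTL4 fell, or 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00437, and adjusted p = 0.276 with an estimated correlation). Those that rose included UCP2, a mitochondrial carrier, from 13.6 ± 0.825 to 28.5 ± 4.26 RPKM, ETFB (0.87), which passes electrons from acyl-CoA dehydrogenases, and TXNIP, from 228.0 ± 10.4 to 418.8 ± 9.99 RPKM. Of 20 lipid droplet and triglyceride genes, 1 rose, AGPAT2 (0.58), or 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.886). Fatty acid synthesis genes had 0 of 20 past the threshold, also 0 adjusted over the list alone (camera adjusted p = 0.838), with FADS3 at 0.40 and PNPLA3 at -0.40. Cholesterol synthesis genes rose in 2 of 25, TM7SF2 (0.92) and FDFT1 (0.45), or 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.886).

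Nuclear genes of the respiratory chain had positive values in 42 of 46 members and cytosolic ribosomal protein genes in 56 of 56, with medians of 0.22 and 0.28, but 0 members of either list passed, also 0 adjusted over the list alone. The camera adjusted p-values were 6.59e-06 and 1.56e-09, with adjusted p = 0.594 and adjusted p = 0.558 with an estimated correlation. The medians depended on scaling: they were 0.14 and 0.10 with quantile normalization and 0.12 and 0.17 with values rescaled to a common sum, where the median of all genes was -0.12. Without PA 3 the ribosomal median was 0.17. The members named by the rule were ATP5F1D (0.73, or 0.47 after removal of the length and GC trend), COX5B (0.58), RPL8 (0.48) and RPL10A (0.48). Both lists consist of short transcripts, with median lengths of 693 and 699 nt, and short transcripts as a class had higher values in PA. Of 13 mitochondrially encoded messenger RNAs, MT-CYB fell (-0.55), also 1 adjusted over the list alone (camera adjusted p = 0.192).

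Immediate early genes rose in 6 of 25 tested members and in 9 adjusted over the list alone, with none lower (camera adjusted p = 6.59e-06, and adjusted p = 0.276 with an estimated correlation). Beside EGR1 they included JUNB (0.94), IER2 (0.66) and DUSP5 (0.59). Of 31 tested ATF4 and integrated stress response targets, 5 rose, among them PCK2 (0.99), ALDH1L2 (0.74) and TRIB3 (0.67), and ATF5 fell (-0.68), with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.255 with an estimated correlation). Chaperones of the endoplasmic reticulum had 0 of 26 past the threshold, also 0 adjusted over the list alone (camera adjusted p = 0.293), with DNAJC3 at -0.46 (-0.29 after removal of the trend) and XBP1 at 0.38. Inflammasome and pyroptosis genes rose in 3 of 10, TXNIP, PYCARD (0.70) and IL1B, or 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00245, and adjusted p = 0.255 with an estimated correlation). TXNIP belongs to both this list and the fatty acid oxidation list. Metallothioneins rose in 3 of 9, MT1L (0.74), MT1E (0.61) and MT1F (0.61), or 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00984, and adjusted p = 0.558 with an estimated correlation), and reads shared within this family make single values uncertain. The list did not pass with protein-coding genes alone (adjusted p = 0.0513) or after removal of the length and GC trend (adjusted p = 0.0568, and 0.0745 with lengths from basic transcripts), and its median of 0.46 was 0.28 without control 3. Rescaling to a common sum moved the medians of the ATF4 list from 0.19 to 0.08 and of the immediate early genes from 0.31 to 0.21. The median of all genes moved with them, from -0.02 to -0.12, and both lists were still past camera.

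NF-kB targets fell in 4 of 28, CCL2 (-1.11), CXCL1 (-0.73), IL6 (-0.66) and CXCL3 (-0.55), while 5 were higher and 7 lower adjusted over the list alone (camera adjusted p = 0.236). Interferon-stimulated genes rose in 2 of 39, ISG20 (0.88) and PSMB9 (0.62), or 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0862). Among 34 extracellular matrix and fibrosis genes 7 fell, including COL3A1, THBS1 (-1.17) and COL12A1 (-0.89), and 2 rose, including CCN2 (0.97), or 8 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0754). Autophagy and lysosome genes went both ways, with 3 of 41 higher and 3 lower, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.703). MAP1LC3A (1.01) and OPTN (0.58) rose, and TFRC (-1.11) and ATP6V0D1 (-0.54) fell. Of 24 apoptosis genes BCL2L1 rose (0.47), or 0 adjusted over the list alone (camera adjusted p = 0.302), and of 20 insulin and growth factor genes TRIB3 rose, also 1 adjusted over the list alone (camera adjusted p = 0.703).

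Only 9 of 37 cardiomyocyte sarcomere and conduction genes reached the expression filter, of which TNNI3 and GJA1 (0.53) rose, or 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.561). TNNI3 was low, at 0.913 ± 0.418 RPKM in control and 3.30 ± 0.695 RPKM in PA. Fibroblast markers fell in 2 of 19, COL3A1 and FAP (-0.74), or 3 adjusted over the list alone (camera adjusted p = 0.236). Smooth muscle markers rose in 2 of 8, TAGLN (0.70) and ACTA2 (0.50), or 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.578). Of 5 epithelial markers KRT8 rose (0.65), or 2 adjusted over the list alone (camera adjusted p = 0.0592). Endothelial and leukocyte markers had 4 and 2 members above the filter, too few for the list test, of which EGFL7 (0.77), TIE1 (0.70) and CD14 (0.72) rose, 2 in each list adjusted over the list alone. Of 25 housekeeping references TFRC, SNRPD3 (-0.82) and PGK1 (-0.51, not past the threshold after removal of the length and GC trend) fell and CHMP2A (0.71) rose, or 4 lower and 1 higher adjusted over the list alone. The median of that list was 0.0056 while camera ranked it lower (camera adjusted p = 0.774).

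**Figure D2:**
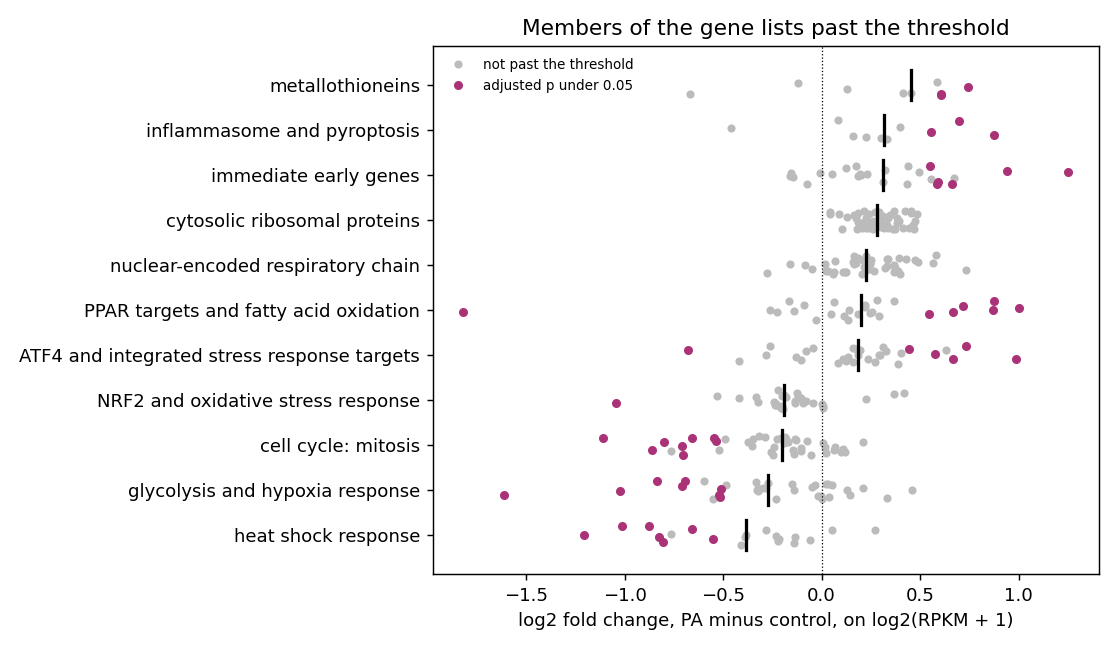
Log2 fold changes (PA minus control, on log2(RPKM + 1), horizontal axis) of the tested members of 11 of the gene lists past the camera threshold. Each point is a gene, coloured where it passed limma, and black bars are medians. Heat shock genes had a median of -0.38 with 7 members past the threshold, and ribosomal protein genes a median of 0.28 with 0.

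Of 34 lists tested, 12 passed camera with the preset correlation of 0.01 and 0 with an estimated correlation, and 10 passed fry. The list that is not reported here is counted among those past camera and past fry. Of the lists past camera, glycolysis and hypoxia (fry adjusted p = 0.0586), metallothioneins (0.122), ribosomal proteins (0.149) and the respiratory chain (0.196) did not pass fry. Interferon-stimulated genes (fry adjusted p = 0.038) and epithelial markers (0.0312) passed fry and not camera. The 5 genes with the highest mean RPKM were MT2A, MT-ND4L, MT-CO1, MT-CO2 and EEF1A1, and none of them passed limma. MT2A was at 17996 ± 3784 RPKM in control and 24342 ± 1901 RPKM in PA, and MT-ND4L at 9741 ± 84.3 and 8028 ± 3759 RPKM.

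Fold changes followed transcript length and GC content across the 11895 protein-coding genes tested. Their median log2 fold change was 0.07 for transcripts up to 1000 nt and -0.15 for those above 4000 nt, and -0.14 below 40% and 0.12 above 60% GC. Genes are not independent replicates, so no test is attached to these values. The slope with length was steepest in PA 3, at -0.10 per doubling, and the slope per 10 points of GC ran from -0.17 in control 3 to 0.09 in PA 1. The length slope of the fold change went from -0.06 to -0.02 without PA 3. With this trend removed from each library, which was chosen after the data were seen, 1893 genes passed limma (1004 higher, 889 lower), including 640 of the 657 original calls that had a length and GC value.

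**Figure D3:**
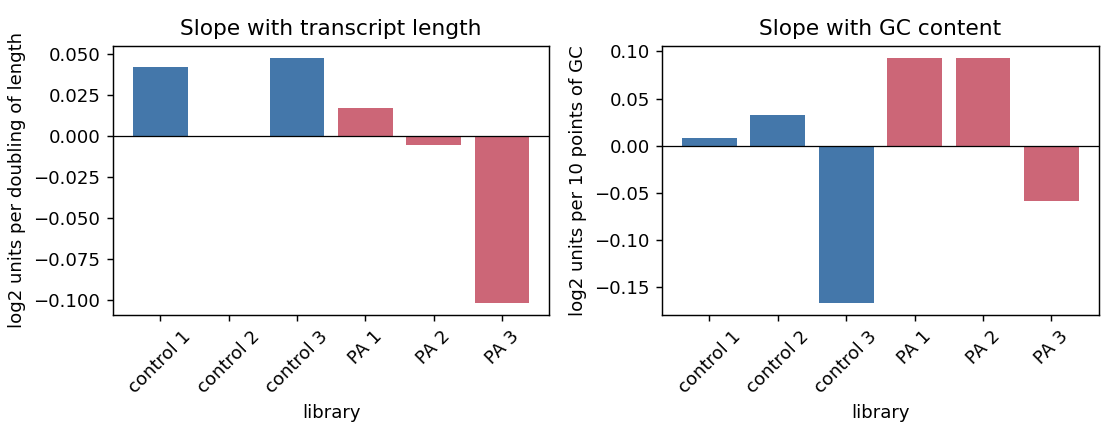
Slopes of each library's log2 deviation from the mean of all libraries against transcript length (left, log2 units per doubling) and GC content (right, log2 units per 10 points), over 11895 protein-coding genes, with control in blue and PA in red. PA 3 had the lowest length slope (-0.10) and control 3 the lowest GC slope (-0.17).

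The libraries were all similar, with Pearson correlations across genes of 0.957 to 0.981. Pairs within a group correlated at 0.975 to 0.981 and pairs between groups at 0.957 to 0.973, except PA 1 with PA 3 (0.967). PA 1 thus correlated better with control 1 (0.973) than with PA 3. The first principal component held 39.0% of the variance and placed the 3 control libraries between -26.5 and -12.0 and the 3 PA libraries between 7.21 and 38.0, with PA 3 farthest out. No 2 libraries were copies of each other, since at most 119 of the 14159 tested genes had equal values in a pair.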

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

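Removal of the length and GC trend in both versions and the use of protein-coding genes alone were chosen after the data were seen, and the version with basic transcripts after the result of the first version. All 681 genes kept their direction in every alternative that tested them. Their PA and control values did not overlap, so most alternatives could not have turned a sign. Only the other scalings and the trend removal could have done so. The count of genes past the limma threshold moved by over 1.5 times in several alternatives: 72 (35 higher, 37 lower) without a filter, which tests 29638 genes, 29 at an adjusted p of 0.01, 85 with an absolute log2 fold change of at least 1, 1157 with protein-coding genes alone, 1893 after removal of the length and GC trend and 2290 with basic transcripts. It ranged from 10 (without PA 2) to 364 (without PA 3) with a library left out, where fewer samples enter the fit, and, after removal of the trend, from 268 (without control 1) to 2084 (without PA 1), with 662 without control 2, 375 without control 3, 337 without PA 2 and 1758 without PA 3. Other scalings, pseudocounts, filters and variance models gave 526 to 934 genes.

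The replicate block, with the replicate number in the fit, gave 98 genes (42 higher, 56 lower). Deviations of same-numbered libraries correlated at 0.16, -0.01 and 0.04. Among the PA libraries, control 1 and control 3 correlated best with their own number, and control 2 with PA 3 (0.12). The numbers were not taken to pair the libraries, but pairing is not excluded.

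The 12 lists past camera became 0 with an estimated correlation (lowest adjusted p = 0.255). Of the 12 lists, 10 passed in all 20 settings with the preset correlation. The 20 settings include the main fit. They also include the variance models, which do not enter camera and so repeated its main result. The NRF2 list reached an adjusted p of 0.0511 without control 2, and metallothioneins were lost with protein-coding genes alone (0.0513) and after removal of the trend (0.0568, and 0.0745 with basic transcripts). Interferon-stimulated genes passed with the first version of the removal (0.0482) and not with basic transcripts (0.0503), so that call rests on the choice of transcripts; over all 20 settings they passed in 5 (adjusted p 0.0102 to 0.221). Other lists that did not pass in the values as deposited passed in some settings: extracellular matrix in 4 of 20 (lowest adjusted p 0.0186), epithelial markers in 4 of 19 (0.00309), mitochondrially encoded messenger RNAs in 3 of 20 (0.00161), histones in 1 of 19 (0.0424) and housekeeping references in 1 of 20 (0.0479).

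Single genes that changed sign, none of them past the threshold, were SIRT1 (-0.1904 to 0.0328 with a library left out, the highest without control 3, and 0.0575 and 0.0525 in the 2 versions of the trend removal), MAPK9 (0.0172 with basic transcripts), SIRT6 (-0.0706 without control 3 to 0.2892 without control 2, -0.0347 and -0.0701 in the 2 versions) and MT-CO1 (-0.0404 rescaled). Rescaling shifts all genes together, and the median of all genes moved from -0.02 to -0.12 with it. The cause of the other sign changes was not tested. MT2A, the highest value in each library, went to 0 with quantile normalization, which gives that rank the same value everywhere. With a library left out, between 26 and 83 of the 87 named genes past the threshold lost it. Count-based tests were not run because the files hold RPKM. Depth is unknown, which limits statements on genes with low values.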

Other observations

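The tests of the length and GC trend by library, and the repeat of the trend removal with basic transcripts, were chosen only after the results they bear on were seen. The added lists of hypoxia-inducible factor and PPAR targets were written after the fall of ANGPTL4 was seen, though before their own tests. They were tested in the same 6 libraries and are not independent support.

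A second set of hypoxia-inducible factor (HIF) targets, 25 genes not in the fixed lists and written down before they were tested, was lower in PA. Negative log2 fold changes were found in 20 of 25, and 4 passed limma, PLOD2 (-0.79), EGLN1 (-0.79), STC1 (-0.62) and FUT11 (-0.61), named here after their values were seen. PLOD2 modifies collagen, and EGLN1 encodes an oxygen-sensing hydroxylase that is itself a HIF target. PLOD2 was at 104.3 ± 12.5 RPKM in control and 59.9 ± 9.10 RPKM in PA (SD, n = 3 per group).

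ANGPTL4, a target of both PPAR and HIF, fell while fatty acid oxidation genes did not. A weaker PPAR response would lower other PPAR targets. The 9 tested targets other than ANGPTL4 went both ways, 5 positive and 4 negative (-0.23 to 0.29), and their median log2 fold change of 0.0634 was smaller than the SD among them (0.18), so this explanation stays open. The sign expected of the median had been fixed before the test without regard to that spread. A weaker hypoxia-type response may account for ANGPTL4 together with CA9, LDHA and ADM. The separate HIF targets were lower after removal of the length and GC trend (camera p = 5.45e-05, and p = 0.0109 with an estimated correlation). These values were not adjusted over lists. With an estimated correlation the fixed lists were tested before the removal and adjusted over all lists. The result therefore does not set the HIF targets apart from the fixed lists. Whether oxygen use, cell density or the treatment itself stands behind a weaker hypoxia-type response was not tested, and the labels give none of these.

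Gene lists moved together between PA and control while fold changes followed length and GC. If the trend were the whole cause, the lists would lose their calls once it is removed. The camera adjusted p after removal was 7.2e-07 for heat shock, 3.12e-05 for glycolysis and hypoxia, 5.46e-05 for mitosis, 3.12e-05 for immediate early genes, 2.44e-06 for ribosomal proteins and 8.36e-05 for the respiratory chain. All 6 also passed with basic transcripts. For heat shock the median stayed at -0.38. With basic transcripts it went from -0.27 to -0.28 for glycolysis and hypoxia and from 0.31 to 0.29 for immediate early genes. In the first version of the removal these medians were -0.30 and 0.28. This argues against the trend as the whole cause for these 3 lists. In the other 3 the median shrank with basic transcripts. It went from 0.28 to 0.18 for ribosomal proteins, from -0.20 to -0.12 for mitosis and from 0.22 to 0.16 for the respiratory chain. The first version gave 0.23, -0.14 and 0.20. There the respiratory chain shrank about as little as the immediate early genes. Lengths and GC contents were medians over annotated transcripts, not over those expressed, so part of the trend may remain. By the rule written before this test, a list that still passed in the same direction counted against the trend, and all 6 did. The size of the median was not part of that rule. Because part of the trend may remain, it was left open as the whole cause for ribosomal proteins, mitosis and the respiratory chain. With an estimated correlation none of the lists passed before the removal, so correlated members remain open.

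The GC part of the trend was not carried by PA 3, whose own GC slope was negative (-0.06). Without PA 3 the slope of the fold change went from 0.08 to 0.1351 log2 units per 10 points of GC. The GC part rested largely on control 3, whose own slope was -0.17, since the slope of the fold change was 0.02 without it. The length part rested largely on PA 3, since its slope per doubling went from -0.0601 to -0.0241 without that library, and the slopes of PA 1 and PA 2 then overlapped those of the controls, which leaves open whether PA 3 accounts for it. The GC slope varied within a group by up to 2.36 times the difference between the group means, which is consistent with a preparation or RNA quality bias that differs from library to library. The treatment stays open as a further cause.

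The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split gave 681 genes and 12 lists. The others gave 0 to 3 genes and 2 to 7 lists, so camera at the preset correlation called lists in every mixed split too. In 1 of the 10 splits, the real one, the counts were as large. A mixed split puts any difference between PA and control into the spread within groups, which lowers its gene count.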
